A study of Homo sapiens with 4 samples.

How the data were processed

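Total RNA was prepared with TRIzol from pellets of cultured cells, labelled with biotin by the WT Terminal Labeling Kit and hybridised to Affymetrix arrays, per the labels' protocols. Probe sets were named through GEO's annotation of the platform. The authors deposited 1 table of log2 expression values, with a row per probe set and a column per array; Affymetrix Expression Console is named in the submitters' processing notes, with no version. Background correction, normalization and summarization are not given in the sources used here. The log2 scale was read from the values, which run from about 2.25 to 14.2 on every array and are not centred per gene. The medians of the 4 arrays lie between 6.80 and 6.84. If the arrays were scaled to each other, which is not given in the sources used here, a change of all transcripts together would not be visible.

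Samples were grouped by site, stomach or ovary, and by implantation round from their titles. Cells were dissociated and cultured for 7 days after round 1, per the series' design text. The description of the round 2 stomach sample names the ovary as the cultured site, and that of the round 2 ovary sample ends by placing the tumour in the stomach. The design text also gives the round 2 ovary sample a name with an added 2 where it lists the RNA samples, and whether that marks a further line is not given in the sources used here. The titles and tissue labels were followed; an exchange of the round 2 samples would change the comparison of sites and leave that of rounds as it is. Each combination of site and round has 1 array. The replicate number of a sample is its round, which is shared by both sites, and deviations from the site means correlated across genes at 0.411 between samples of the same round (2 pairs), so fits with a replicate block (the round between sites, the site between rounds) stand beside the fits without it where a call differs.

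Of 33297 rows, 19460 carry 1 gene symbol in the platform annotation, 1754 carry several and 12083 are unnamed here; rows with several were not used. Symbols were updated through the gene identifier to a RefSeq gene table of assembly GRCh38.p14, in which 19429 of the single-gene rows were found and 31 were not. That table served for names and for the order of neighbouring genes only, and no coordinates are given because the values name no genome build. The rows represent 18417 genes, of which 769 have over 1 row; the probe set with the highest mean was used. Genes whose mean over the 4 arrays exceeded the 30th percentile of all rows (5.64) were tested, which left 14547 genes and removed 3870.

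Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on all 4 arrays, once for ovary minus stomach and once for round 2 minus round 1. Each fit had 2 residual degrees of freedom, or 1 with the block. The interaction of site and round was fitted in the same way as a contrast of the round 1 stomach and round 2 ovary arrays with the other two, a test chosen after the data were examined. Gene lists (34, with 855 genes) were fixed before the data were examined, and 33 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 33 lists. The red blood cell list had 2 measured genes and was not tested. Camera was repeated with a correlation estimated per list, and fry was run as a further test. Counts of genes at least 2-fold apart in single-array differences have no p-value. The rule for naming genes was fixed before the data were examined. Ranked genes and list members were then picked by their differences on these same 4 arrays, so large differences were selected. For the sites, the genes named are the 12 highest and 12 lowest in ovary by the smaller of the within-round differences of equal sign. For the rounds they are the 8 highest and 8 lowest by the within-site differences, and for the interaction the 5 largest per direction. A panel of 12 genes and up to 4 members per list, by the size of the mean difference, were added. The alternatives were no signal minimum, a minimum at the 50th percentile, quantile normalization, centring on medians, other choices among a gene's probe sets, a trended or robust prior, the replicate block, an adjusted p threshold of 0.10, fold thresholds of 1.5 and 3, and leaving out each array. Figures were drawn with matplotlib 3.10.9.

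The fit for ovary minus stomach was tested on simulated data with the real means of the 14547 genes, the fitted prior spread and 200 changed genes, in 10 runs per size. At a 2-fold change limma recovered 30.6% of the changed genes with a mean of 4 false calls, and at a 4-fold change 93.4% with 11. A list of interferon genes shifted by -0.17, the mean site difference of that list in the data, was called by camera in 10 of 10 runs at 2-fold and 9 of 10 at 4-fold. The simulated noise was independent between genes, so these runs do not test camera where the genes of a list are correlated. It was also independent between arrays, with no difference between rounds. In the data the round difference lies in the residual of this fit, so the recovered shares may not hold for the real comparison of sites.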

Results

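RNA from the human gastric carcinoma cell line SNU-16 was profiled after growth in mice. The cells were implanted into the stomach wall of immunodeficient BALB/c nude mice, and cells were recovered from the tumour in the stomach wall and from metastases in the ovary. Recovered cells were cultured and implanted again, stomach-derived cells giving a stomach tumour and ovary-derived cells an ovarian metastasis of round 2. The data are 4 arrays, 1 for each combination of 2 sites (stomach and ovary) and 2 rounds of implantation, so each site has 2 arrays. Per the labels, the round 2 lines descend from the round 1 lines of the same site, so the spread between the arrays of a site is the spread between successive passages of 1 lineage and may be partly technical. Values are on a log2 scale, with medians over all 33297 rows between 6.80 and 6.84 on the 4 arrays, and the number of arrays limits the precision of every comparison. Below, a level is the mean ± SD of the n = 2 arrays of a site, a difference is ovary minus stomach or round 2 minus round 1 in log2 units, and the error of a fitted difference is limma's standard error.

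The comparison of sites asked which transcripts differed between cells from ovarian metastases and cells from stomach tumours. The gene furthest apart was ELOVL5, a fatty acid elongase acting on polyunsaturated chains (probe set 8127145). Its level was 6.80 ± 0.010 in ovary and 4.83 ± 0.21 in stomach, a 3.93-fold difference seen in round 1 (1.83) and in round 2 (2.12). The stomach level lay under the signal minimum of 5.64, so this fold was measured from near the floor of the array. PROM1, which encodes the surface glycoprotein CD133, was also near that floor, with 5.08 ± 0.31 in stomach and 6.21 ± 0.045 in ovary. KRT20, an intestinal-type keratin, stood at 6.48 ± 0.68 in ovary and 5.51 ± 0.33 in stomach, also under the minimum. HBEGF, a ligand of the EGF receptor, was 2.22-fold higher on average, by 0.62 in round 1 and 1.69 in round 2.

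Of the genes ranked lowest in ovary, TFF1, which encodes a trefoil peptide of the gastric surface mucosa (probe set 8070579), had the largest mean difference. It was 2.78-fold lower, with 10.12 ± 0.058 in stomach and 8.64 ± 0.99 in ovary. Its difference was -2.13 in round 1 and -0.82 in round 2. The membrane mucin MUC17 differed by -0.95 ± 0.26, and SPINK1, a trypsin inhibitor, by -0.60 ± 0.29. NXPH4, a neurexophilin (probe set 7956395), was the lowest by the smaller of its within-round differences, -0.84 and -0.92, with levels of 7.66 ± 0.11 in ovary and 8.55 ± 0.054 in stomach. BTN3A1, a butyrophilin recognised by gamma delta T cells, differed by -0.80 ± 0.13. HCP5, a transcript of the MHC region, differed by -0.66 ± 0.12. Enzymes in this group were the monooxygenase FMO5 (-0.76 ± 0.21), the cytidine deaminase CDA (-0.77 ± 0.23), the aminoacylase ACY3 (-0.59 ± 0.087) and the phosphodiesterase GDPD3 (-0.64 ± 0.13). The arrestin-domain gene ARRDC3 differed by -0.86 ± 0.29 and GRAMD1B, a sterol transporter, by -0.68 ± 0.26.

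The remaining genes ranked highest in ovary were PIWIL1, a germline Argonaute protein, at 0.89 ± 0.18, and TBC1D9 at 0.88 ± 0.18. GPRIN3 (0.94 ± 0.60), the adaptor GRB10 (0.85 ± 0.53), the GTPase RAB38 (0.81 ± 0.35), TBL1X (1.06 ± 0.51) and VWA5B1 (0.81 ± 0.46) were higher in ovary in each round but lower in round 2 than in round 1 at each site. GLI3, a transcription factor of Hedgehog signalling, was higher in ovary (0.74 ± 0.50) and higher in round 2 (1.05 ± 0.35).

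**Figure D1:**
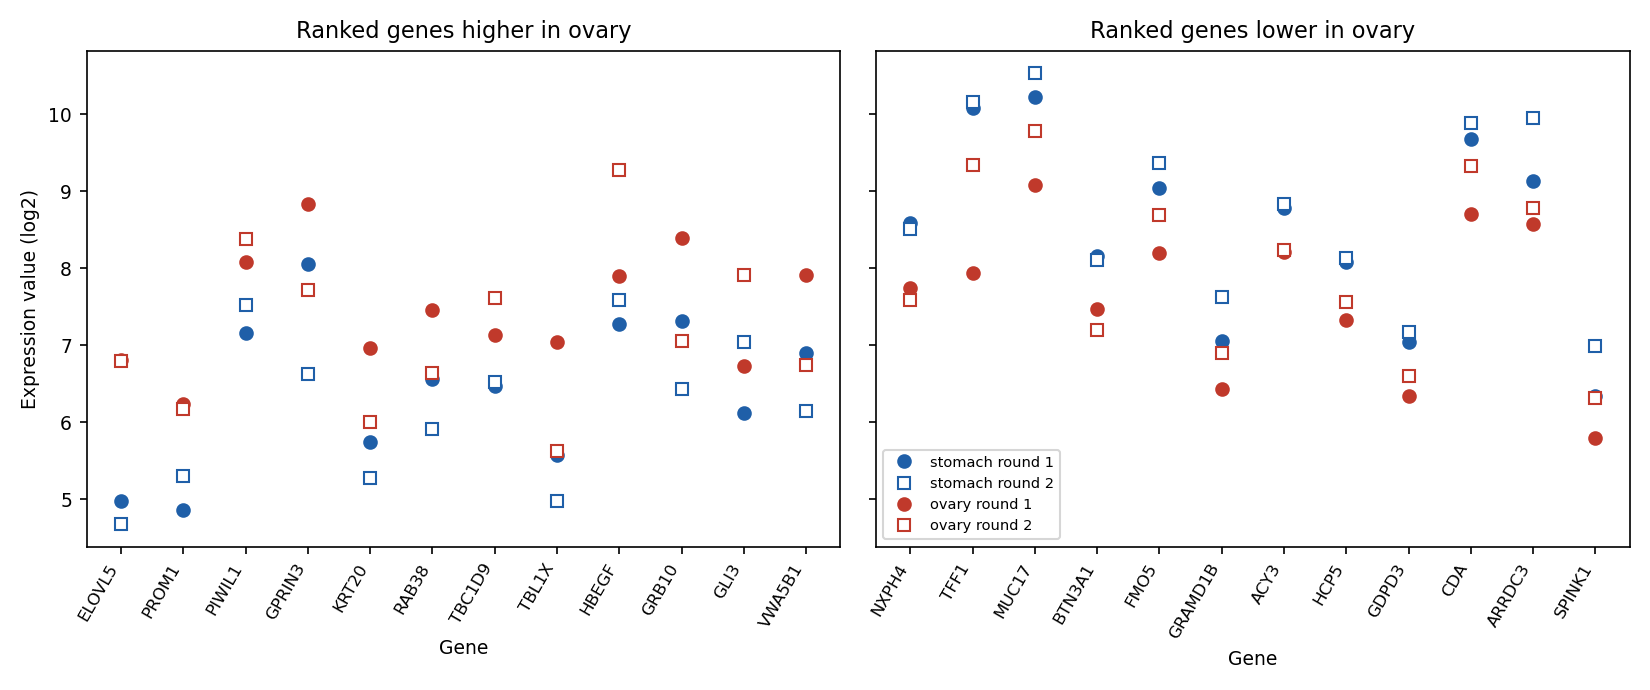
Log2 expression (vertical axis) on the 4 arrays of the 12 genes ranked highest and the 12 ranked lowest in ovary, with 1 point per array, stomach in blue, ovary in red, filled circles for round 1 and open squares for round 2. By the rule of the ranking, in each round the red point lies above the blue one for the genes on the left, such as ELOVL5, and below it for those on the right, such as TFF1.

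None of these differences passed the test across all genes. Of 14547 genes, limma called 0 between sites, with a smallest adjusted p of 0.578 for ELOVL5, and 378 had an unadjusted p under 0.05 where chance gives 727.4. This fit leaves the round difference in the residual, which raises p-values, so 378 does not show fewer differences than chance. With the round as a replicate block, 0 genes were called and the smallest adjusted p was 0.122. In that fit 916 genes had an unadjusted p under 0.05, against the same 727.4. The residual of that fit holds the interaction alone and genes are not independent, so this count does not by itself show an effect of the site. A difference of at least 2-fold in the same direction in both rounds was found in 1 gene, ELOVL5, while 2 genes were at least 2-fold apart in opposite directions. Across the tested genes, which are not independent replicates, the site difference of round 1 correlated with that of round 2 at r = 0.101. In single-array comparisons, 63 genes were at least 2-fold apart between the sites in round 1 and 32 in round 2.

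**Figure D2:**
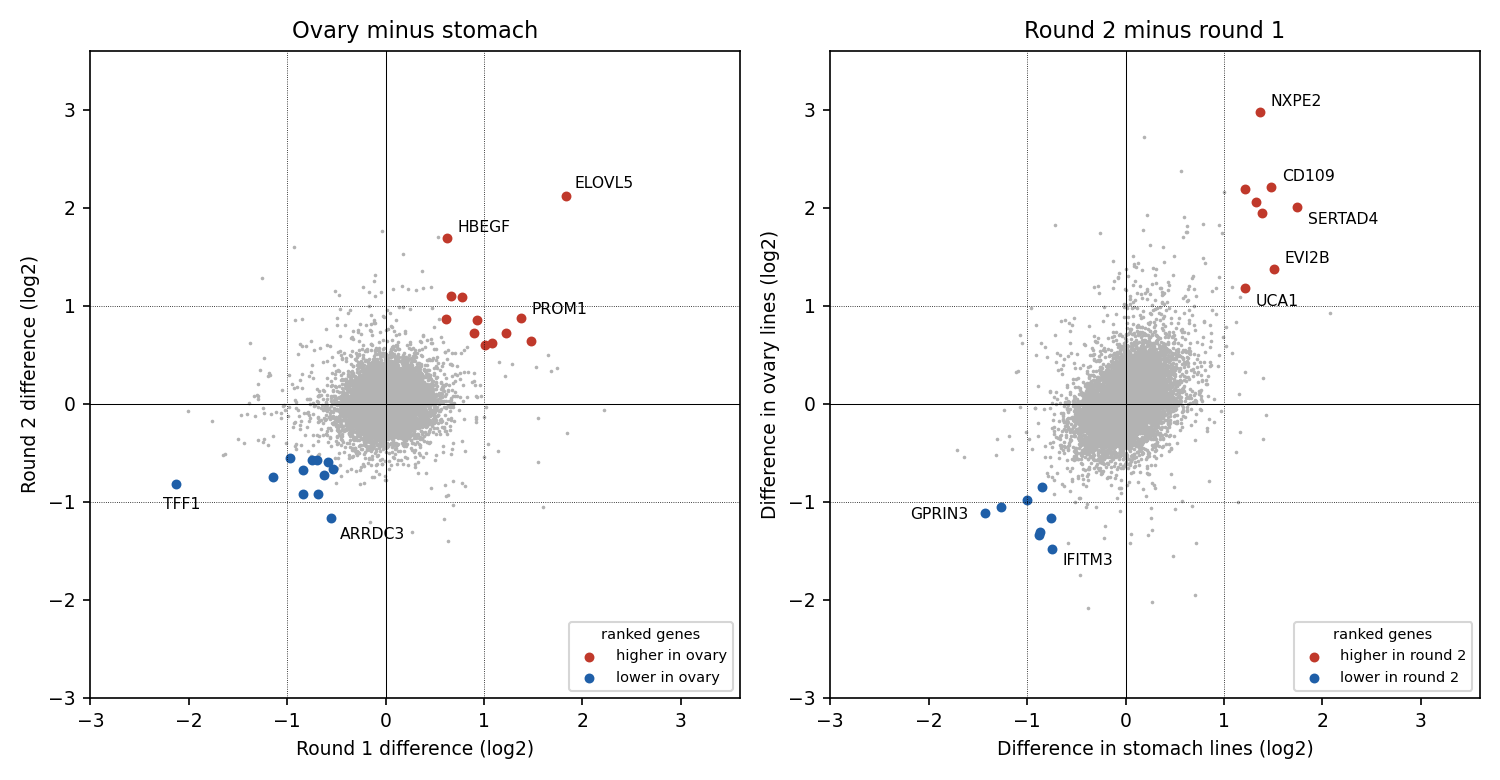
Log2 differences of the 14547 tested genes (grey, ranked genes in colour, dotted lines at 2-fold): left, ovary minus stomach in round 1 (horizontal) and round 2 (vertical), and right, round 2 minus round 1 in stomach (horizontal) and ovary lines (vertical). The left cloud has little slope (r = 0.101 across genes) and the right cloud a steeper one (r = 0.411).

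Genes of antigen presentation were lower in ovary as a group. Of the 14 measured members of the MHC list, 11 were lower in ovary (camera adjusted p = 6.28e-05, but adjusted p = 0.71 with an estimated correlation). The median difference was -0.34 in round 1 and -0.090 in round 2. The members furthest apart were PSMB9, an immunoproteasome subunit (-0.65 ± 0.14), the peptide transporter subunit TAP1 (-0.52 ± 0.18), the aminopeptidase ERAP2 (-0.51 ± 0.13, with its ovary level under the signal minimum) and the class I light chain B2M (-0.29 ± 0.12). Of 28 measured interferon response genes, 21 were lower in ovary (camera adjusted p = 0.00669, and adjusted p = 0.71 with an estimated correlation). SAMD9L differed by -0.92 ± 0.66, SAMD9 by -0.80 ± 0.68 and the oligoadenylate synthetase OAS2 by -0.73 ± 0.46, whereas IFITM3, a restriction factor against viral entry, went the other way (0.79 ± 0.55). The median interferon difference was -0.16 in round 1 and -0.055 in round 2. The interferon call ended without the round 1 ovary array (adjusted p = 0.549), without the round 2 stomach array (adjusted p = 0.156) and without the signal minimum (adjusted p = 0.0894). Of 11 measured leukocyte markers, 9 were lower in ovary (adjusted p = 0.225), with CD68 at 9.89 ± 0.0020 in stomach and a difference of -0.28 ± 0.12, and NKG7 at 7.32 ± 0.17 and -0.21 ± 0.13. Of endothelial markers, 8 of 9 were lower (adjusted p = 0.262). Leukocyte markers fixed for a separate test were at low levels, the median of PTPRC, LAPTM5, TYROBP, FCER1G, AIF1 and CSF1R being 5.76 in stomach, and their median site difference was -0.062.

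Genes of the unfolded protein and amino acid stress responses were higher in ovary. Of 22 measured members, 17 were higher (camera adjusted p = 0.000477, and adjusted p = 0.71 with an estimated correlation). The median difference was 0.22 in round 1 and 0.15 in round 2. The members furthest apart were TRIB3, a pseudokinase (0.51 ± 0.15), the cystine transporter subunit SLC7A11 (0.48 ± 0.096), CHAC1, which degrades glutathione (0.46 ± 0.15), and the stress sensor SESN2 (0.43 ± 0.12). The p53 target list, which shares SESN2, had 16 of 20 members higher in ovary (camera adjusted p = 0.00759, and adjusted p = 0.71 with an estimated correlation). Its median difference was -0.014 in round 1 and 0.34 in round 2. The exonuclease AEN (0.70 ± 0.28), the metabolic regulator TIGAR (0.70 ± 0.23, with its stomach level under the signal minimum) and the cell cycle inhibitor CDKN1A (0.55 ± 0.39) were furthest apart, and CDKN1A differed by -0.045 in round 1 and 1.14 in round 2. The p53 call ended without the round 2 ovary array (adjusted p = 0.846, direction reversed), without the round 1 stomach array (adjusted p = 0.38) and without the round 2 stomach array (adjusted p = 0.0753). The immediate early and heat shock list, which reads handling of cells, had the same shape, with medians of -0.12 in round 1 and 0.42 in round 2, and was not called (adjusted p = 0.105).

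**Figure D3:**
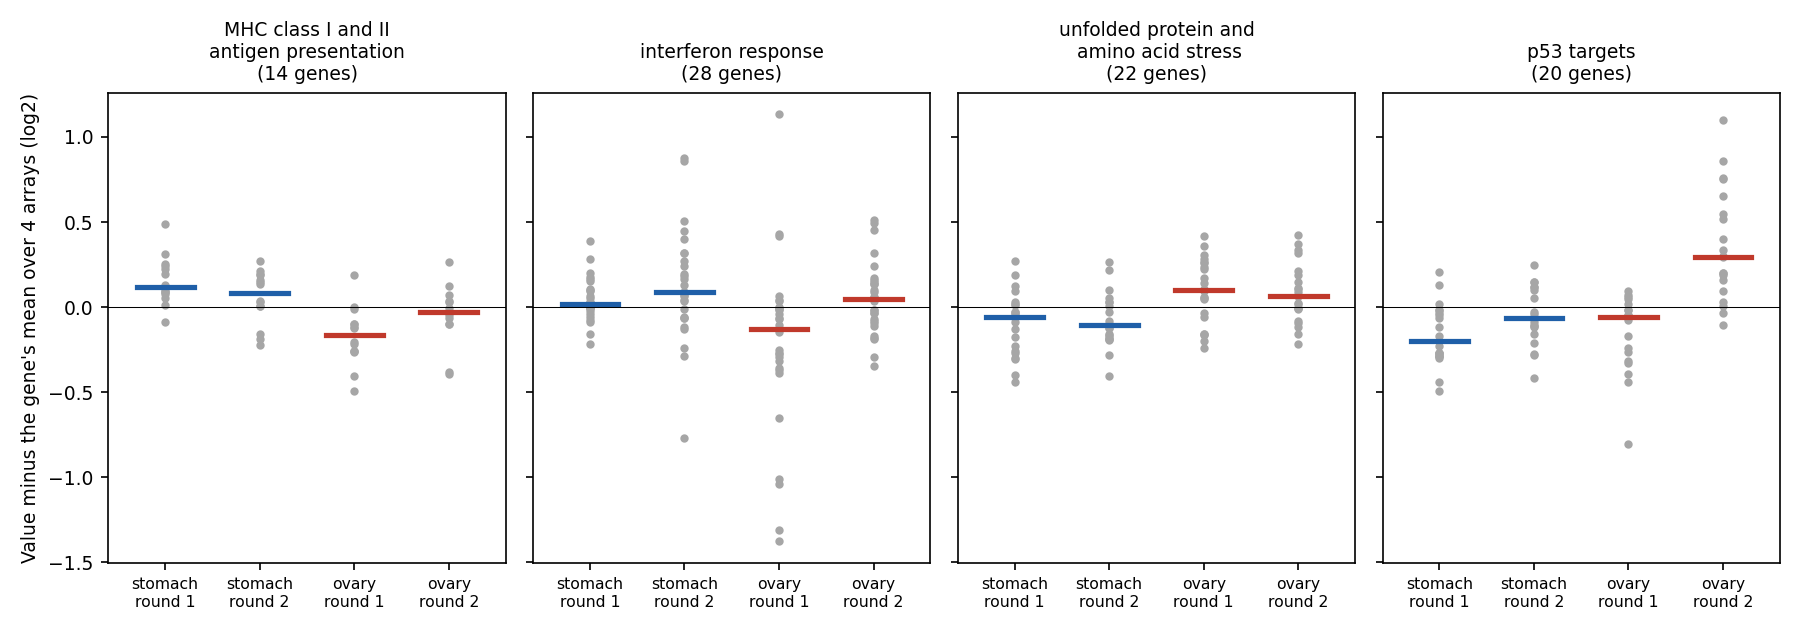
Values on the 4 arrays of the measured members of the 4 gene lists called between sites, where each grey point is 1 gene on 1 array, as its log2 value minus the gene's mean over the 4 arrays, and bars are medians over the list (blue stomach, red ovary). The median of the p53 list is highest on the round 2 ovary array.

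The adjusted p of 0.71 with an estimated correlation was shared by these 4 lists and none was called. Before adjustment, camera with an estimated correlation gave p = 0.104 (MHC), 0.140 (interferon), 0.0441 (unfolded protein) and 0.368 (p53). None of the members of these 4 lists passed the test across all genes, and 0 passed when adjusted over the list alone. Among the other lists, adjusted over the list alone, 1 member passed in the intestinal list (DPP4, 0.57 ± 0.087) and 1 in the stem cell list (PROM1, 1.13 ± 0.17). Lineage lists were not called: 18 of 25 intestinal genes were lower in ovary (adjusted p = 0.262), with TFF3 at -0.81 ± 0.22 and KRT20 in the other direction, and 11 of 20 gastric genes (adjusted p = 0.228), with LYZ at -0.55 ± 0.36. Epithelial adhesion genes were lower in 24 of 34 (adjusted p = 0.105), though not CLDN1 (1.05 ± 0.44), and mesenchymal genes in 8 of 17 (adjusted p = 0.764). Of HOX genes, 12 of 18 were lower (adjusted p = 0.108), led by HOXB6 (-0.48 ± 0.16). TGF-beta and BMP targets were higher in 11 of 18 (adjusted p = 0.0888), led by ID1 (0.64 ± 0.14), and hypoxia and glycolysis genes lower in 19 of 29 (adjusted p = 0.0888). Markers of other cells were not called, the leukocyte and endothelial lists included: fibroblast matrix (adjusted p = 0.688), mesothelial (adjusted p = 0.95), and ovarian steroidogenic and follicle genes (adjusted p = 0.513).

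Genes at the loci amplified in SNU-16 had strong signals, and CD44, FGFR2 and MYC differed between sites by less than the larger of their 2 SDs. CD44 stood at 13.32 ± 0.065 in stomach and 13.36 ± 0.065 in ovary, FGFR2 at 12.93 ± 0.0074 and 12.92 ± 0.033, and MYC at 12.16 ± 0.29 and 12.38 ± 0.042. The amplified-locus list was higher in ovary in 7 of 13 members (adjusted p = 0.496). CDH1, which encodes E-cadherin, differed by -0.018 ± 0.10, and VIM, which encodes vimentin, lay below the signal minimum with 4.97 ± 0.11 in stomach and 5.01 ± 0.12 in ovary. EPCAM, an epithelial adhesion molecule, differed by -0.21 ± 0.090, and both of its probe sets were lower in ovary in each round. The remaining members of this panel were ERBB2 (-0.18 ± 0.11), MET (-0.073 ± 0.10), the proliferation marker MKI67 (0.019 ± 0.12) and the intestinal transcription factor CDX2 (-0.075 ± 0.11). No single-gene row named MUC5AC.

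The comparison of rounds asked what differed between lines recovered after the second implantation and those recovered after the first. Ranked first in round 2, by the smaller of its differences at the 2 sites, was SERTAD4 (probe set 7909503), 3.67-fold higher on average, by 1.75 in stomach lines and 2.01 in ovary lines. CD109, a membrane co-receptor that binds TGF-beta, was 3.6-fold higher (1.85 ± 0.32), and DAPP1, an adaptor of B cell receptor signalling, 3.17-fold (1.67 ± 0.19). DKK1, a secreted WNT antagonist, differed by 1.21 in stomach and 2.19 in ovary. ZFP42, a marker of pluripotent cells, differed by 1.33 and 2.06, from levels under the signal minimum in round 1. EVI2B (1.44 ± 0.093), NXPE2 (2.17 ± 0.44) and the long non-coding RNA UCA1 (1.20 ± 0.079) completed the highest genes. Lower in round 2 were the monocarboxylate transporter SLC16A7 (-1.16 ± 0.12), the amino acid transporter SLC43A1 (-0.99 ± 0.14), SEMA6A (-1.09 ± 0.16), FAM221A (-0.85 ± 0.096), IFITM3 (-1.11 ± 0.41), GPRIN3 (-1.27 ± 0.45), GRB10 (-1.11 ± 0.41) and VWA5B1 (-0.96 ± 0.39).

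Of 14547 genes, limma called 0 between rounds, with a smallest adjusted p of 0.149, and 2178 had an unadjusted p under 0.05 where chance gives 727.4. With the site as a replicate block, 0 were called and 2358 had an unadjusted p under 0.05. The residual of the first fit holds the site difference and the interaction, and that of the blocked fit the interaction alone. Because both are smaller than the round difference and genes are not independent, these counts against 727.4 do not by themselves show an effect of the round. There were 12 genes at least 2-fold apart in the same direction at both sites, 10 higher and 2 lower in round 2, against 1 in opposite directions. The round difference in stomach correlated across genes with that in ovary at r = 0.411. Of the sum of squares between the 4 arrays over all tested genes, the round took 51.5%, the site 26.6% and the interaction of site and round 21.9%, where equal parts would be 33.3%. The ovary arrays differed in 130 genes at least 2-fold between rounds and the stomach arrays in 38.

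Cell cycle genes, immediate early and heat shock genes, and p53 targets were higher in round 2 as groups. The immediate early and heat shock list reads handling of cells, and handling was not tested as a cause. Of 41 cell cycle genes, 30 were higher (camera adjusted p = 0.001, and adjusted p = 0.792 with an estimated correlation), led by CCNE2, cyclin E2 (0.99 ± 0.16), and the kinetochore gene NDC80 (0.51 ± 0.14). This call ended without the round 1 stomach array (adjusted p = 0.132). Immediate early and heat shock genes were higher in 20 of 24 (camera adjusted p = 0.001, and adjusted p = 0.792 with an estimated correlation), with FOS at 0.80 ± 0.22, the phosphatase DUSP1 at 0.79 ± 0.36 and JUN at 0.75 ± 0.32. Their median difference was 0.042 in stomach and 0.48 in ovary, and the call ended without the round 1 ovary array (adjusted p = 0.129) or the round 2 ovary array (adjusted p = 0.184). Of p53 targets, 17 of 20 were higher (camera adjusted p = 0.00183, and adjusted p = 0.792 with an estimated correlation), with TP53INP1 at 1.25 ± 0.34 and the p53 ligase MDM2 at 0.68 ± 0.28. The medians were 0.10 in stomach and 0.38 in ovary, and the call ended without the round 2 ovary array (adjusted p = 0.165) or the round 1 stomach array (adjusted p = 0.0529).

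Epithelial adhesion, integrin, receptor tyrosine kinase and cholesterol synthesis lists were also higher in round 2. Median differences in stomach and ovary lines were 0.054 and 0.22 for epithelial adhesion genes and 0.18 and 0.19 for integrins. They were 0.032 and 0.20 for receptor tyrosine kinases, and 0.077 and 0.13 for cholesterol synthesis. Epithelial adhesion genes and keratins were higher in 26 of 34 (camera adjusted p = 0.001, and adjusted p = 0.792 with an estimated correlation), with KRT7 at 1.58 ± 0.33, the protease ST14 at 0.44 ± 0.099 and CLDN1, a tight junction claudin, in the other direction (-0.64 ± 0.59). Of markers of other cells, lower in round 2 were 10 of 11 fibroblast matrix genes (adjusted p = 0.144), 10 of 11 leukocyte genes (adjusted p = 0.27), 8 of 9 endothelial genes (adjusted p = 0.221) and 8 of 9 ovarian steroidogenic and follicle genes (adjusted p = 0.0611), with none of these lists called without the block. Their median differences were small, at -0.087, -0.053, -0.070 and -0.14. The members furthest apart had stomach levels of 6.22 ± 0.20 (PDGFRB), 5.93 ± 0.19 (CD14), 7.12 ± 0.79 (ESAM, higher in round 2) and 8.71 ± 0.42 (ZP3). The first 2 lay near the signal minimum of 5.64, so the counts alone do not show a loss of such cells. Integrins and adhesion receptors were higher in 14 of 23 (camera adjusted p = 0.0492, and adjusted p = 0.792 with an estimated correlation), with CEACAM1 at 0.98 ± 0.31 and ITGA3 at 0.53 ± 0.090; this call ended without any 1 of the 4 arrays (adjusted p from 0.124 to 0.196), without the signal minimum (adjusted p = 0.0936), with arrays centred on their medians (adjusted p = 0.0543) and with a trend in the prior (adjusted p = 0.0614). Receptor tyrosine kinases and ligands were higher in 17 of 22 (camera adjusted p = 0.0392, and adjusted p = 0.792 with an estimated correlation), with EPHA2 at 0.49 ± 0.15 and TGFA at 0.41 ± 0.14. That call ended without the signal minimum (adjusted p = 0.171) and without the round 1 ovary array (adjusted p = 0.333), the round 2 stomach array (adjusted p = 0.124) or the round 2 ovary array (adjusted p = 0.113). Cholesterol synthesis genes were higher in 14 of 16 (camera adjusted p = 0.0189, and adjusted p = 0.792 with an estimated correlation), led by STARD4 (0.45 ± 0.089), and the call ended without the round 1 ovary array (adjusted p = 0.166) or the round 2 stomach array (adjusted p = 0.121). Metallothioneins, which bind zinc and copper, were the 1 list lower in round 2, in 8 of 10 members (camera adjusted p = 0.00928, and adjusted p = 0.792 with an estimated correlation), with MT1H at -0.49 ± 0.077 and MT1E at -0.32 ± 0.076. Metallothionein genes are near-identical copies whose probes may share transcripts, so the members are uncertain one by one.

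With the site as a replicate block, 12 lists were called, the same 8 and 4 more. These were hypoxia and glycolysis (higher, blocked adjusted p = 0.0341), interferon response (higher, 0.0401), matrix proteases (higher, 0.0478) and ovarian steroidogenic genes (lower, 0.0478). With the block and an estimated correlation, the adjusted p of each of these 4 lists was 0.86. Without the block their adjusted p values were 0.0929, 0.132, 0.144 and 0.0611. Among interferon genes, SAMD9 (1.39 ± 0.43), SAMD9L (1.31 ± 0.50) and GBP2 (1.00 ± 0.34) were higher in round 2 and IFITM3 (-1.11 ± 0.41) lower. Adjusted over the list alone, 2 cell cycle genes (CCNE2 and KIF11), 2 metallothioneins (MT1E and MT1H) and 1 p53 target (POLH, 0.55 ± 0.070) passed among the called lists, and 0 in the remaining 5.

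Some genes differed between sites in opposite directions in the 2 rounds, or in 1 round. A half-interaction of at least 2-fold was found in 8 genes, against 13 for the mean site difference and 38 for the mean round difference. PLK2, a polo-like kinase, differed between ovary and stomach by -0.93 in round 1 and 1.60 in round 2, CCDC190 by -1.25 and 1.28, and TTN, the gene of titin, by -1.38 and 0.62. The protease inhibitor SERPINA1 went from -2.01 to -0.072 and the maltase MGAM from -0.038 to 1.77. In the other direction were NETO2 (2.22 and -0.068), the sulfotransferase UST (1.84 and -0.30), the membrane adaptor PAG1 (1.55 and -0.60), the spliceosomal RNA RNU4-2 (1.60 and -1.05) and the small nucleolar RNA SNORA22 (0.64 and -1.40). Over 119 small nucleolar RNA genes the median site difference was 0.13 in round 1 and -0.12 in round 2. Of the lists, ovary minus stomach was higher in round 2 than in round 1 for immediate early and heat shock genes (camera adjusted p = 2.24e-06), mesenchymal genes (camera adjusted p = 0.0218) and p53 targets (camera adjusted p = 0.0288), and lower for histones (camera adjusted p = 0.00152). With an estimated correlation, the adjusted p of each of these 4 lists was 0.942. The histone list was fixed as a reading of RNA preparation and the immediate early list as a reading of handling, so the calls of both may be technical. Of 14547 genes, limma called 0, with 194 at an unadjusted p under 0.05 where chance gives 727.4 and a smallest adjusted p of 1. A model with site, round and interaction leaves no residual degrees of freedom, so these tests set the interaction against a residual that holds the site and round differences.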

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

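The test of chance placement along chromosomes, and the use of the third split as a test of the change of the site difference between rounds, were chosen after the results were seen; the remaining tests in this part were chosen before.

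The site difference of several results had opposite signs in the 2 rounds. Its change from round 1 to round 2 is the contrast of the round 1 stomach and round 2 ovary arrays with the other two, in which limma called 0 of 14547 genes (194 at an unadjusted p under 0.05, smallest adjusted p of 1), with the site and round differences left in the residual. The change of the site difference from round 1 to round 2 was 2.54 for CCDC190, 2.53 for PLK2, 2.00 for TTN and 1.80 for MGAM. It was -2.65 for RNU4-2, -2.29 for NETO2, -2.15 for UST, -2.14 for PAG1 and -2.04 for SNORA22. Panel genes with small differences also crossed 0, with changes of 0.057 for FGFR2, -0.17 for MET, -0.11 for MKI67 and 0.17 for CDX2. Among lists, the median site difference in round 2 minus that in round 1 was 0.36 for p53 targets (camera adjusted p = 0.0288), 0.54 for immediate early and heat shock genes (camera adjusted p = 2.24e-06), -0.090 for cell cycle genes (camera adjusted p = 0.0541) and 0.059 for metallothioneins (camera adjusted p = 0.703). The median round difference was opposite at the 2 sites for the MHC list, by 0.16 (camera adjusted p = 0.0748), and for the unfolded protein list, by -0.094 (camera adjusted p = 0.836). With an estimated correlation, the adjusted p of each of these 6 lists was 0.942.

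Antigen presentation and interferon genes were lower in ovary lines with the preset correlation but not called with an estimated one (adjusted p = 0.71 for both), and the interferon call also ended without ovary replicate 1 (adjusted p = 0.549), without stomach replicate 2 (adjusted p = 0.156) and without the signal minimum (adjusted p = 0.0894). Fewer leukocytes in the ovary cultures were tested as an explanation. The median level of 6 leukocyte genes on the stomach arrays was 5.76, below the 6.82 median of all rows, and their largest difference between the stomach arrays was 0.22, while CD68 (9.89 ± 0.0020) and NKG7 (7.32 ± 0.17) lay above that median and differed by -0.28 and -0.21 between sites. For the 6 genes, a level below that median by more than 0.22 was set in advance as the outcome against this explanation, and it was met. Their median site difference was -0.062, against -0.21 for the MHC list. The host is a mouse, and human probes read mouse transcripts poorly. That would weaken a mouse contribution to the MHC and interferon values as well as to the 6 genes. Mouse RNA was not measured and CD68 and NKG7 go with the explanation, so it is not excluded. Drift of a cell lineage cannot be told apart from the site, because the labels give 1 lineage per site, apart from an unexplained sample name in the design text; the site itself remains an untested biological explanation.

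Round 2 differed from round 1 more than ovary from stomach. A technical shift of all rows between rounds may contribute: among 9989 rows below the signal minimum, taken as mostly unexpressed, the round difference in stomach correlated with that in ovary at 0.211 (bootstrap 95% interval 0.177 to 0.244). That is 0.513 of the 0.411 found among tested genes, just over the 0.5 set in advance, and the lower end of the interval falls under that share. For unequal carry-over of small RNA, a shift of small nucleolar RNAs with the same sign at both sites was set in advance. They differed from protein-coding genes by -0.22 between rounds in ovary and by 0.074 in stomach, so that outcome was not met. The outcome set against this explanation, a small shift at both sites, was not met either, so it stays open. Handling of cells was not tested as a cause. The immediate early and heat shock list, which reads it, had 20 of 24 genes higher in round 2, with medians of 0.042 in stomach and 0.48 in ovary. A second implantation as a biological difference remains untested beside these.

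Neighbouring genes differed together in single-array comparisons. From PPWD1 to ENC1, a stretch chosen after its values were seen, 33 of 34 genes were lower in ovary than in stomach in round 1 (median -0.39), while the round 2 median was 0.019 and that of round 2 minus round 1 in ovary 0.50. The largest median of 15 neighbouring genes in that comparison was -0.45, beyond the 0.35 reached in 1000 shuffles of gene order, which argues against chance placement. A copy-number difference kept by each lineage was tested on the mean site difference. Genes 10 places apart correlated at 0.0085, within the 0.026 reached by shuffles, which argues against such differences over much of the genome. A correlation over all genes cannot exclude a few short stretches. The 1 stretch of 15 genes past the shuffles was FOXM1 to AKAP3 (0.246 against 0.244). Its medians had the same sign, 0.36 in round 1 and 0.038 in round 2. Stretches also stood out between rounds in the stomach lines. From GPR83 to CUL5, likewise chosen after its values were seen, 28 of 29 genes were higher in round 2 (median 0.39). The median of these genes between rounds in ovary was 0. Genes 10 places apart correlated at 0.073 in the stomach round difference and 0.073 in the mean round difference, beyond the 0.023 and 0.027 reached by shuffles. Changes in single lines may remain, untested, such as a change in the round 1 ovary line that its round 2 descendants lack.

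With 4 arrays there are 3 ways to form 2 groups of 2, too few for a share under 0.05. The real split by site called 4 lists, and the highest of the other splits called 8; 3 of the 3 splits called at least 4. The split by round called 8 lists, 1 of the 3 splits reached that number, and the highest of the others called 4. The third split, the same contrast as the change of the site difference between rounds, also called 4 lists: immediate early and heat shock genes, histones (0.00152), mesenchymal genes (0.0218) and p53 targets, the values being camera's adjusted p. All 4 were at 0.942 with an estimated correlation. The immediate early list reads handling of cells and the histone list RNA preparation. If the round 2 samples had been exchanged, which their conflicting descriptions leave open, this split would be the comparison of sites; the MHC (0.0748), interferon (0.458) and unfolded protein lists (0.836) were not called in it.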

How the results depend on the processing

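All alternatives given in this part were chosen before the data were examined. Gene counts between sites and between rounds were 0 in every setting run, including each array left out (0 to 0) and the replicate block (0 and 0). With an estimated correlation, 0 lists were called between sites and 0 between rounds. Fry called 0 and 0, with 2 and 3 lists at an unadjusted p under 0.05, and its mixed test, for change in either direction, called 0 and 6; neither compares a list with other genes. Lists between sites numbered 11 above the 50th percentile, where fewer genes were tested, and lists between rounds 12 with the replicate block; the block changed no other call. Leaving out 1 array gave 3 to 9 lists between sites and 4 to 6 between rounds, with 1 residual degree of freedom and the lone array of a group assumed to vary like the others. The MHC and unfolded protein lists were called in each of these, and p53 targets reversed without ovary replicate 2 (adjusted p = 0.846, against 1.39e-08 to 0.846 over the 4 arrays left out). The count of genes at least 2-fold apart between sites in both rounds (1) became 0 above the 50th percentile and 19 at 1.5-fold, against 22 in opposite directions. Between rounds (12) it became 78 at 1.5-fold, against 14 in opposite directions, and 1 at 3-fold. The count of interaction genes (8) became 5 above the 50th percentile, 74 at 1.5-fold and 0 at 3-fold. The fold and signal thresholds act by their own construction; the cause of the other changes was not tested. Without a signal minimum, 12 of the 12 genes highest and 11 of the 12 lowest in ovary remained in the ranking, and 7 of 8 in each direction between rounds. An offset of 16 was not run because the values were already log2, and camera has no robust option, so robust list tests were not run. Low signal limits ELOVL5, PROM1, KRT20, TBL1X, EVI2B, ZFP42, FAM221A, PLK2, MGAM, ERAP2 and TIGAR, whose lower means lie under the minimum.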

Other observations

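Other fixed lists were not called and are given as values. Between sites, immune signalling lists were at adjusted p = 0.262 (inflammatory and NF-kB targets, 15 of 24 lower, with the iron-sequestering lipocalin LCN2 at -0.66 ± 0.20) and 0.331 (chemokine receptors and ligands). Growth and adhesion lists were at 0.228 (receptor tyrosine kinases), 0.336 (integrins) and 0.196 (matrix proteases, with TIMP1 at -0.38 ± 0.21). Cell cycle genes were at 0.34, WNT targets at 0.579 and stem cell genes at 0.34. Metabolic lists were at 0.228 (cholesterol synthesis, 14 of 16 lower), 0.874 (xenobiotic metabolism), 0.827 (metallothioneins) and 0.368 (steroid receptors). Cancer testis antigens were at 0.336, histones at 0.336 and ribosomal proteins at 0.383.

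Between rounds, the xenobiotic list was not called as a group (adjusted p = 0.94), yet 5 of its members passed when adjusted over the list alone, in both directions, and fry's mixed test called it (adjusted p = 0.022), as it did cell cycle, matrix protease, ribosomal protein and ovarian genes (each at the same value) and endothelial genes (0.0424). The drug efflux pump ABCG2 differed by -0.59 ± 0.10 and the reductase AKR1C1, whose family has close copies, by -0.42 ± 0.075. ABCC2 (0.41 ± 0.086), HMOX1 (0.31 ± 0.073) and GCLM (0.44 ± 0.11) went the other way. Single members passed in the same way in lists that were not called: CD109 (mesenchymal, 0.94), ESAM (endothelial, 0.221), ZP3 (ovarian, 0.0611), IL32 (inflammatory, 0.377), ABCG2 (stem cell, 0.94) and H2BC21 (histones, 0.58), the value being the adjusted p of the list. ESAM, an endothelial adhesion molecule, was at 0.97 ± 0.12, while 8 of the 9 endothelial markers were lower in round 2. ZP3, a zona pellucida protein, was at -0.63 ± 0.069. The remaining lists were at adjusted p = 0.144 (fibroblast matrix), 0.27 (leukocyte), 0.221 (chemokines), 0.221 (TGF-beta), 0.221 (ribosomal proteins), 0.638 (steroid receptors) and 0.94 (intestinal, gastric, mesothelial, MHC, WNT, unfolded protein, HOX, cancer testis and amplified-locus genes). Median, mean and test direction of a list differed in sign for 3 lists between sites and 11 between rounds, the lowest adjusted p among them being 0.368 and 0.580.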
